A study of Gallus gallus with 48 samples.

How the data were processed

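Gene expression was measured in primary cells from the anterior pituitary gland of chicken embryos at embryonic day 11, dispersed and kept in serum-free medium, per the labels' protocols. Cells received corticosterone (CORT, the main avian glucocorticoid, at 1e-09 M) over 6 durations (none, then 1.5 h, 3 h, 6 h, 12 h and 24 h), either directly or after 1.5 h with cycloheximide (CHX, an inhibitor of translation, at 10 micrograms per ml). The 12 groups held 4 replicates each, 48 samples in all, which the labels call biological replicates without saying whether they came from separate dispersions, so that p-values measure the spread between these samples. The group at 0 h without CHX is called untreated and that at 0 h after CHX is called CHX alone. Only 0 h groups lacked CORT, so that duration of CORT and time in culture ran together in every comparison with CORT. The sample titles do not say whether CHX was removed before CORT, so that "after CHX" gives the order alone.

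Per the labels' protocols, total RNA was amplified as antisense RNA from an oligo(dT) primer carrying a T7 promoter. Each sample was labelled with Cy3 and hybridised to a 2-colour cDNA array against a Cy5 pool made from all 48 samples. The labels speak of fewer slides than samples for the split of the pool, and this was not resolved. The deposited table held 1 log2 ratio per probe and array, 19200 probes on 48 arrays. The base of the logarithm was read from the values. Of 739065 values other than 0, 637 equalled, to 8 decimals, the log2 of a ratio of whole numbers below 200, against 76 for the natural logarithm and 129 for log10, so the reading rests on few values. Background correction, normalisation and software were not given in the sources used here. The deposited log2 ratios had array medians of -0.038 to 0.048 and array SDs of 0.301 to 0.324, and every print block lay within 0.025 of 0, so that the values had been centred by block and scaled before deposit. Such scaling removes any difference in total RNA and can compress large changes. Between 14609 and 16840 probes had a value on each array. Exact zeros made up 2.34% of values, 99.7% of them in probes measured on 24 or fewer arrays. No spot intensities were used here, so that signal over background is unknown and precision is set by the number of arrays.

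The sign of the ratio is not stated. Values were read as sample over pool, a direction called likely because FKBP5, a classical glucocorticoid target, was higher after CORT in all 10 comparisons with CORT. GH and DUSP1, also named for this check beforehand, gave no clear change, and TSC22D3, PER1, NR3C1, LHB and CGA were not analysed here. If the sign were opposite, every direction given would turn.

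The probe annotation gave 1 gene symbol for 10601 probes, several for 0 and none for 8599. The gene identifiers of 10455 of the named probes were found in the current RefSeq gene table (assembly GRCg7b), and the other 146 kept the older symbol. No coordinates are given because the array's annotation names no genome build. Probes of 1 symbol were averaged on the log2 scale and unnamed probes were kept singly. A feature needed a value on at least 3 of the 4 arrays in each of the 12 groups. This left 11207 of 15027 features, 5644 named genes and 5563 unnamed probes, with 0.87% of values missing. The largest share of equal nonzero values between 2 arrays was 0%, so each was counted as 1 sample.

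All 48 arrays were fitted in 1 group-means model with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8), with 36 residual degrees of freedom for complete features. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The 11 comparisons set each CORT group against its 0 h group and CHX alone against untreated. A moderated F-test over 5 interaction contrasts asked whether the response to CORT differed after CHX. Intervals are 95% confidence intervals of the fitted log2 difference.

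The 21 gene lists covered glucocorticoid-induced genes, pituitary hormones and secretory genes, pituitary transcription factors, immediate-early and short-lived genes, cell cycle genes, ribosomal proteins, amino acid response and unfolded protein response, heat shock proteins, cholesterol synthesis, oxidative phosphorylation, proteasome subunits, interferon and antiviral genes, NF-kB and cytokine genes, circadian clock genes, steroid receptor and chaperone genes, and markers of fibroblasts and matrix, red blood cells, neurons and glia, endothelium, immune cells, and cartilage and muscle. They were tested with limma's camera statistic on the moderated statistics, because some values were missing, at a preset correlation between genes of 0.01 and with the named genes as background. Adjustment ran over 231 list tests. Camera with a correlation estimated from the residuals, and fry, which tests whether a list's genes move on balance one way, were alternatives. Both were run with missing values set to their group mean. The tests were first run against all features, which called 44 list tests. The gene-level background stated in the design calls 39 and is the one reported.

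Samples, tests, lists, named genes and most alternatives were fixed before the data were examined. For each comparison the named genes were those past the threshold with the 6 largest increases and 6 largest decreases whose 4 treated replicates all lay on one side of the control mean (12 and 12 for CHX alone and for CORT at 24 h). Added to these were the 10 genes with the smallest joint interaction p, up to 10 genes called with and without CHX at 1.5 or 3 h, up to 4 members per list, the hormones and the genes of the direction check. At most 2 unnamed probes that rose and 2 that fell are named. The result of 1 gene that the rule names for CHX alone is not reported here.

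The procedure was tested on simulated data for CORT at 24 h without CHX, with 200 of 11207 features changed over 20 runs. It recovered 34.2% of changes of 0.5 on the log2 scale, 88.4% of changes of 1, 98.4% of changes of 1.5 and 99.5% of changes of 2, with a false share of 0.7%. With arrays reassigned and no change added, no run gave a call in that comparison, no comparison gave more than 3, and 2 of 20 runs gave joint interaction calls (up to 146). The list tests then gave a median of 14.5 calls of 231 at the preset correlation (highest 31) and a median of 0 with an estimated correlation (highest 3). An earlier version drew arrays with replacement, gave up to 92 calls in that comparison and 449 in any, and list calls with a median of 11.5 (highest 36). Neither version kept the replicate numbers balanced over the groups, as they are in the real arrays. These rates, the false share among them, therefore need not hold for the real arrays.

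The alternatives were a block for the replicate number, median centring, quantile normalisation, fitting only the groups compared, single probes, other filters, array weights, a variance trend, leaving out each array, and 7 choices made after seeing the data.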

Results

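The series recorded how corticosterone changed gene expression in cultured cells of the embryonic chicken pituitary, and which responses were also seen after cycloheximide. It held 48 two-colour cDNA arrays, 4 for each of 12 groups, with 14609 to 16840 probes measured per array. Over all probes, array pairs correlated between -0.76 and 0.87, and pairs within a group between -0.69 and 0.79 (median 0.3, against 0.09 between groups). The dyes ran the same way on every array per the labels, so no array was turned. Negative correlations were also found within groups, so they do not come from opposite treatments alone, and what caused them was not established here. A single axis held 51.6% of the spread within groups. Its score went in part with the replicate number, with means of -0.19, 0.053, 0.003 and 0.134 for numbers 1 to 4. What arrays of equal number share is not known here. Genes of ribosomal proteins followed that axis (median correlation 0.72 across arrays, over genes that are not independent), as did heat shock, oxidative phosphorylation and proteasome genes (each 0.63), while cartilage and muscle (-0.78), endothelial (-0.74) and immune cell markers (-0.73) ran against it. Values below are log2 ratios to the pool of all samples, as mean ± SD, and differences are log2 with their SE.

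**Figure D1:**
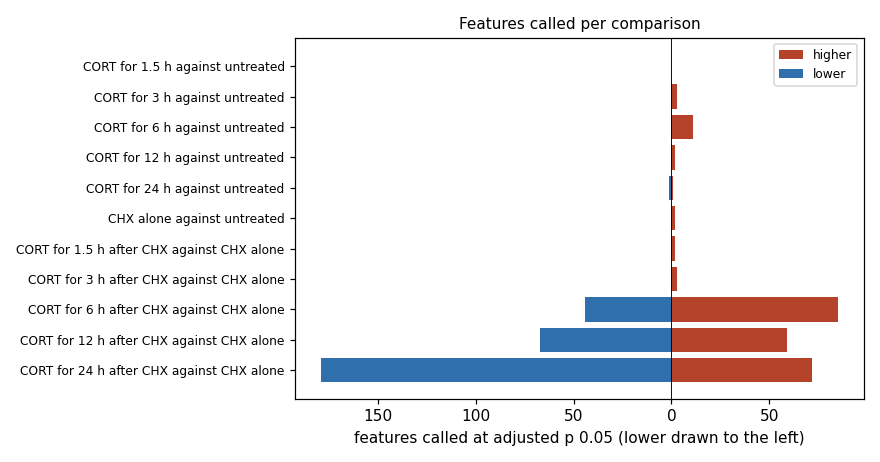
Number of features (named genes and unnamed probes, of 11207 tested) past an adjusted p of 0.05 in each of the 11 comparisons, drawn to the right where higher and to the left where lower. Without CHX the counts lay between 0 and 11, and at 6, 12 and 24 h after CHX they were 129, 126 and 251.

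The first question was which genes responded to CORT without CHX. At 1.5 h no single gene passed, but the glucocorticoid-induced genes rose as a list of 17 (adjusted p = 0.000274, and 0.00578 with an estimated correlation), 15 of them above 0. None passed over all features, and 3 passed adjusted over the list alone, each higher in 4 of 4 samples: RASD1, a Ras-related protein induced by dexamethasone (0.8, SE 0.24), FKBP5, a co-chaperone of the glucocorticoid receptor (0.65, SE 0.2), and PDK4, a mitochondrial kinase that restrains pyruvate oxidation (0.49, SE 0.16). The count of 0 features from limma compares with 672 at an unadjusted p under 0.05, and the smallest adjusted p was 0.125. Array weights turned the count of 0 into 34.

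At 3 h of CORT, RASL10A, a small GTPase of the Ras family, rose from -1.08 ± 0.29 to 0.84 ± 0.23 (n = 4 each), a difference of 1.92 (SE 0.28, adjusted p = 0.000458). FKBP5 rose from -1 ± 0.23 to 0.01 ± 0.11 (difference 1.01, SE 0.2, adjusted p = 0.0472), and the unnamed probe_13.4.10 rose by 2.03 (adjusted p = 0.0206). These 3 were the features called, all higher, with 203 at an unadjusted p under 0.05. The glucocorticoid-induced list rose again (adjusted p = 0.000192, and 0.00553 with an estimated correlation), with 1 member called over all features and 2, FKBP5 and RASD1, adjusted over the list alone. Circadian clock genes rose as a list (8 of 9 above 0, adjusted p = 0.00414, and 0.00904 with an estimated correlation), among them PER2 (0.42) and HLF (0.29), with 0 single members called. The amino acid and unfolded protein response list fell (14 of 16 below 0, adjusted p = 0.00966, and 0.0281 with an estimated correlation), also with 0 members called. It is called the unfolded protein response list below, but it also holds amino acid response genes such as ASNS and PHGDH. Its changes do not tell these responses apart. Proteasome genes were lower and endothelial markers higher at the preset correlation (adjusted p = 0.00261 and 0.0482), and both calls were lost with an estimated correlation (adjusted p = 0.42 and 0.661). Of these, proteasome genes followed the axis of spread and endothelial markers ran against it. Without any one of untreated replicates 1, 2 and 4 or CORT 3 h replicates 2, 3 and 4, only 1 feature remained past the threshold. FKBP5 lost its call in 14 of 22 alternative settings, among them the same leave-outs and CORT 3 h replicate 1, and RASL10A kept its call in all.

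At 6 h, 11 features rose and 0 fell, 8 of them at least 2-fold, and 6 were named. RASL10A reached 1.32 ± 0.55 (difference 2.40, adjusted p = 2.08e-06). IMP3, whose gene identifier was not in the current table, rose by 1.24 (SE 0.22, adjusted p = 0.00489), PRRG3, a membrane protein with a vitamin K-dependent domain, by 1.16 (adjusted p = 0.0237), and CCDC80, a secreted protein of the matrix, by 1.05 (adjusted p = 0.0383). FKBP5 rose by 1.05 (adjusted p = 0.00968), with 1.63 and 0.48 at its 2 probes, and LRRN3, a leucine-rich repeat membrane protein, by 0.89 (adjusted p = 0.00489). The glucocorticoid-induced list was called higher at the preset correlation (adjusted p = 0.0118; adjusted p = 0.0725 with an estimated correlation). The number at an unadjusted p under 0.05 was 231. The count was 5 without untreated replicate 1, 4 without untreated replicate 2, 7 without CORT 6 h replicate 2 and 3 without CORT 6 h replicate 3, and 1 when the arrays numbered 1 were left out of every group. Without CORT 6 h replicate 3, the differences of IMP3, PRRG3, CCDC80, FKBP5 and LRRN3 (1.17, 1.06, 0.93, 1.03 and 0.78) no longer passed, and RASL10A passed in every setting.

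At 12 and 24 h without CHX, RASL10A was the named gene called. It stood at 0.38 ± 0.38 at 12 h (difference 1.46, SE 0.28, adjusted p = 0.0423) and at 0.70 ± 0.46 at 24 h (difference 1.78, SE 0.28, adjusted p = 0.00217). FKBP5 differed from untreated by 0.76 at 12 h (adjusted p = 0.99) and 0.62 at 24 h (adjusted p = 0.999). Each time gave 2 features, the others being an unnamed probe that rose at 12 h and probe_48.10.20, which fell by 0.63 at 24 h (adjusted p = 0.0309), with 283 and 243 features at an unadjusted p under 0.05. Clock genes were higher as a list at 12 h (8 of 9 above 0, adjusted p = 0.0249, and 0.0412 with an estimated correlation), and no list was called at 24 h. Ribosomal protein genes were lower at 12 h at the preset correlation (34 of 44 below 0, adjusted p = 0.0267), but adjusted p = 0.841 with an estimated correlation. At 12 h the count was 0 or 1 in each leave-out that moved it; at 24 h it was 0 without CORT 24 h replicate 4, where RASL10A differed by 1.6 (adjusted p = 0.052). RASL10A at 12 h lost its call in 12 of 21 settings, and the clock list at 12 h lost its call without CORT 12 h replicate 1 or 2 or untreated replicate 4 (adjusted p = 0.0571, 0.112 and 0.123).

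The second question was what CHX did alone. After 1.5 h of CHX, immediate-early and short-lived genes rose together (13 of 15 above 0, adjusted p = 8.49e-14, and 1.69e-15 with an estimated correlation). Over all features 0 members passed, and adjusted over the list alone 5 passed: JUN, a subunit of AP-1 (0.89 ± 0.24 against -0.62 ± 0.37, difference 1.51, adjusted p = 0.0707 over all features), ID3, an inhibitor of helix-loop-helix factors (0.86), HES4, a Hairy-related repressor (0.54), MCL1, a short-lived survival protein (0.43), and BTG2, an antiproliferative gene. Of the 2 features called, both higher, DUSP7, a MAP kinase phosphatase, rose by 0.47 (SE 0.08, adjusted p = 0.0134, higher in 4 of 4 samples), with 262 features at an unadjusted p under 0.05. Pituitary hormone and secretory genes fell as a list (13 of 17 below 0, adjusted p = 0.0119, and 0.0106 with an estimated correlation), with 0 members called. TSHB, the beta subunit of thyrotropin, differed by -0.86 (SE 0.31, adjusted p = 1). Ribosomal protein genes were lower at the preset correlation (adjusted p = 0.00123), with adjusted p = 0.714 with an estimated correlation. The count of 2 features was 0 without untreated replicate 2 or 4 or CHX replicate 1 or 3, and the same 0 when only these 2 groups were fitted. The hormone and secretory list lost its call without untreated replicate 1 or 2 or CHX replicate 2 or 4 (adjusted p = 0.0541, 0.137, 0.0577 and 0.107) and with fry (adjusted p = 0.0684).

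The third question was which genes responded to CORT after CHX. At 1.5 h PDK4 rose from -0.41 ± 0.37 to 0.44 ± 0.40 (difference 0.85, SE 0.16, adjusted p = 0.0197), and the glucocorticoid-induced list rose with it (12 of 17 above 0, adjusted p = 3.41e-07, and 5.88e-05 with an estimated correlation; 4 members adjusted over the list alone, PDK4, RASD1, FKBP5 and BCL6, and 1 over all features). Cholesterol synthesis genes fell as a list (14 of 18 below 0, adjusted p = 0.000671, and 0.0287 with an estimated correlation), as did the immediate-early list (9 of 15 below 0, adjusted p = 0.00475, and 0.00553) and the unfolded protein response list (14 of 16 below 0, adjusted p = 0.00578, and 0.0178), with 0 members of these called over all features and ID2 alone adjusted over its list. The other feature called was the unnamed probe_1.1.1 (2.41, adjusted p = 0.01), the corner spot of its print block. Of 17 corner spots tested, 1 was called at 1.5 and 3 h and 2 at the later times. Heat shock and ribosomal protein genes were lower at the preset correlation (adjusted p = 0.00467 and 0.00116), and these calls were lost with an estimated correlation (adjusted p = 0.144 and 0.714). PDK4 lost its call in 11 of 22 alternative settings, and the count of 2, with 258 at an unadjusted p under 0.05, was 0 without CHX replicate 1 or 3 or CORT 1.5 h after CHX replicate 2 or 3.

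At 3 h after CHX, FKBP5 rose from -1 ± 0.58 to 0.05 ± 0.32 (difference 1.05, SE 0.2, adjusted p = 0.025). Cholesterol synthesis genes fell (14 of 18 below 0, adjusted p = 0.000164, and 0.0141 with an estimated correlation), with 4 members adjusted over the list alone, FDFT1 (squalene synthase), HMGCS1, HSD17B7 and MSMO1, and 0 over all features. Immediate-early genes fell (12 of 15 below 0, adjusted p = 0.000671, and 0.000645), with BTG2, ID2 and ID3 adjusted over the list alone. The glucocorticoid-induced list was higher at the preset correlation (adjusted p = 0.0087; adjusted p = 0.0552 with an estimated correlation). Adjusted over the list alone 6 members rose and SCNN1A, a subunit of the epithelial sodium channel, fell (-0.51, SE 0.13). Endothelial markers were higher and ribosomal protein genes lower (adjusted p = 0.0221 and 0.000742), and neither held with an estimated correlation (adjusted p = 0.587 and 0.712). The 3 features called, with 761 at an unadjusted p under 0.05, became 1 without CHX replicate 3 or replicate 3 of this group, 7 and 9 without CHX replicates 2 and 4 and 21 without replicate 4 of this group. They became 0 when only the 2 groups were fitted or the arrays numbered 1 were left out, and 1477 with array weights. FKBP5 lost its call without CHX replicate 1 or 3 or replicate 3 of this group (differences 0.99, 0.8 and 0.94).

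At 6 h after CHX, 85 features rose and 44 fell (74 and 60 with quantile normalisation), 33 of the 129 at least 2-fold, and 82 were named genes (52 up, 30 down). FKBP5 rose from -1 ± 0.58 to 0.82 ± 0.15 (difference 1.82, SE 0.2, adjusted p = 3.43e-07) and IMP3 by 1.83 (SE 0.22, adjusted p = 1.29e-06). PRRG3 rose by 1.57 (adjusted p = 0.000109). EDN2, an endothelin (1.68), TAF1D, a component of the RNA polymerase I machinery (1.45), and PTBP2, a splicing regulator (1.35), also rose, with adjusted p of 0.0277, 0.0164 and 0.00974. Among the glucocorticoid-induced genes (adjusted p = 0.00182, and 0.0178 with an estimated correlation) 4 rose over all features: FKBP5, PDK4 (0.99), NFKBIA, the inhibitor of NF-kB (1.26), and BCL6, a transcriptional repressor (0.84). Adjusted over the list alone 5 rose and 1, SCNN1A, fell.

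Genes of sterol synthesis fell at 6 h after CHX. The list (15 of 18 below 0, adjusted p = 4.46e-09, and 8.46e-05 with an estimated correlation) had 6 members called over all features and 8 adjusted over the list alone. FDFT1 fell from 0.62 ± 0.69 to -1.25 ± 0.80 (difference -1.87, SE 0.41, adjusted p = 0.00992), MSMO1, a sterol demethylation enzyme, by 1.56 (adjusted p = 0.00413), and HSD17B7 and CYP51A1 by 0.56 and 0.48. AGTR1, an angiotensin receptor, fell by 1.85 (SE 0.31, adjusted p = 0.000364), HEY1, a Notch target repressor, from 0.86 ± 0.56 to -0.86 ± 0.44 (difference -1.72, adjusted p = 0.00118), and KLF11, a zinc finger factor, by 1.23 (adjusted p = 0.0138). SYDE2 fell by 1.11 (adjusted p = 0.0487), yet 1 of its 2 probes stood at 0.03. Immediate-early genes fell (12 of 15 below 0, adjusted p = 7.29e-05, and 5.07e-05), with HES4 and ID3 called over all features and 3 adjusted over the list alone. The unfolded protein response list fell (15 of 16 below 0, adjusted p = 0.000527, and 0.00382) with 0 members called, and clock genes rose (8 of 9 above 0, adjusted p = 0.0102, and 0.0178), with HLF, a clock-controlled transcription factor, called (0.67). The number at an unadjusted p under 0.05 was 1080, and no other list was called. The count was 68 and 42 without replicates 1 and 3 of this group, 51 without CHX replicate 3, and 15 when only the 2 groups were fitted. Without replicate 3 of this group FDFT1, MSMO1, KLF11, EDN2, TAF1D, PTBP2 and SYDE2 no longer passed (-1.64, -1.34, -1.16, 1.6, 1.4, 1.21 and -0.9), and KLF11 differed by -0.6 without CHX replicate 1, whereas FKBP5, IMP3 and PRRG3 passed in every setting.

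At 12 h after CHX, 59 features rose and 67 fell. IMP3 (1.71), PRRG3 (1.67) and FKBP5 (1.42) remained higher, with adjusted p of 7.15e-06, 2.8e-05 and 2.8e-05. LHFPL5, a membrane protein (1.01), HPGD, the dehydrogenase that inactivates prostaglandins (1.00), and CRIM1, a membrane regulator of bone morphogenetic protein signals (0.98), rose with adjusted p of 0.00939, 0.00409 and 0.0236. FDFT1 fell by 1.91 (SE 0.41, adjusted p = 0.0121), the beta-tubulin TUBB4B by 1.49 (adjusted p = 0.0257), KLF11 by 1.44 (adjusted p = 0.0037), HEY1 by 1.37 (adjusted p = 0.0166), RCN1, a calcium-binding protein of the endoplasmic reticulum, by 1.36 (adjusted p = 0.0166), and JUN from 0.89 ± 0.24 to -0.42 ± 0.37 (difference -1.31, adjusted p = 0.0272). In untreated cells JUN stood at -0.62 ± 0.37, so that its level after this fall was still higher. FDFT1 (-0.02 ± 0.71 untreated) and HEY1 (0.31 ± 0.23) ended below their untreated levels, at -1.29 ± 0.72 and -0.51 ± 0.7. The lists moved as at 6 h. Cholesterol synthesis fell (15 of 18 below 0, adjusted p = 6.83e-06, and 0.00382 with an estimated correlation; 3 members called, 8 adjusted over the list alone), immediate-early genes fell (9 of 15 below 0, adjusted p = 0.0102, and 0.0106; 3 called, 5 over the list alone) and the unfolded protein response list fell (11 of 16 below 0, adjusted p = 0.00173, and 0.00822; 0 called, 5 over the list alone, among them HSPA5, the endoplasmic reticulum chaperone, and ASNS, asparagine synthetase). Clock genes rose (9 of 9 above 0, adjusted p = 0.00182, and 0.00553; HLF called at 0.72) and so did glucocorticoid-induced genes (14 of 17 above 0, adjusted p = 0.00116, and 0.0141; 3 called). Ribosomal protein genes were lower (38 of 44 below 0, adjusted p = 0.000473), with adjusted p = 0.666 with an estimated correlation. The count of 126, with 42 at least 2-fold and 1278 at an unadjusted p under 0.05, was 48 and 35 without replicates 1 and 3 of this group, 28 and 77 without CHX replicates 3 and 4, and 1 when only the 2 groups were fitted. Without CHX replicate 3 the calls of HPGD (0.85), CRIM1 (0.81), LHFPL5 (0.81), FDFT1 (-1.78), TUBB4B (-1.38), HEY1 (-1.27), RCN1 (-1.13) and JUN (-1.3) ended, and KLF11 differed by -0.81 without CHX replicate 1.

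At 24 h after CHX, 72 features rose and 179 fell, 83 of the 251 at least 2-fold, and of the named genes 31 rose and 111 fell. Among named genes the largest decreases were in SALL1, a zinc finger developmental regulator (0.47 ± 0.35 to -1.52 ± 0.45, difference -1.99, SE 0.39, adjusted p = 0.00218), KLHL14, a kelch protein (-1.97, SE 0.29, adjusted p = 7.79e-05), THBS2, a matrix glycoprotein (-1.95, SE 0.33, adjusted p = 0.000365), HPGDS, a prostaglandin synthase (-1.94, SE 0.45, adjusted p = 0.0116), FDFT1 (-1.73, adjusted p = 0.0134) and AP4M1, an adaptor subunit of vesicle traffic (-1.68, adjusted p = 0.0101). The unnamed probe_40.3.15 fell by 2.37 (adjusted p = 0.000189). Fibroblast and matrix markers fell as a list (15 of 19 below 0, adjusted p = 2.87e-05, and 0.0142 with an estimated correlation), with 4 called over all features: OGN (-1.21), MGP (-1.10), ACTA2, smooth muscle actin (-0.74), and FN1, fibronectin (-0.69). IMP3 (1.40), PTBP2 (1.27), FKBP5 (1.26), CRIM1 (1.11), LHFPL5 (1.00) and SLTM (0.96) rose, with adjusted p of 0.000203, 0.0117, 0.000207, 0.00333, 0.00436 and 0.00245.

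Cholesterol synthesis at 24 h after CHX was lower (14 of 18 below 0, adjusted p = 2.87e-05, and 0.00657 with an estimated correlation), with 5 members called, among them FDPS, farnesyl diphosphate synthase (-1.41), and MSMO1 (-1.19), and 6 adjusted over the list alone. Immediate-early genes were lower (10 of 15 below 0, adjusted p = 2.13e-05, and 1.14e-05), with 4 called, ID3 (-1.48), BTG2 (-0.91), ID2 (-0.68) and HES4 (-0.5), and 5 adjusted over the list alone. The unfolded protein response list was lower (12 of 16 below 0, adjusted p = 0.00578, and 0.0178; 0 called, 4 over the list alone). Ribosomal protein genes were lower (37 of 44 below 0, adjusted p = 0.000192, but adjusted p = 0.658 with an estimated correlation), with RPL10A called (-0.74). The number at an unadjusted p under 0.05 was 1366. The count was 118 and 94 without replicates 2 and 4 of this group, 116 without CHX replicate 3, and 139 when only the 2 groups were fitted. Without replicate 4 of this group HPGDS, FDFT1, AP4M1, PTBP2 and LHFPL5 no longer passed (-1.75, -1.64, -1.61, 1.22 and 0.86), and SALL1, KLHL14 and THBS2 passed in every setting.

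**Figure D2:**
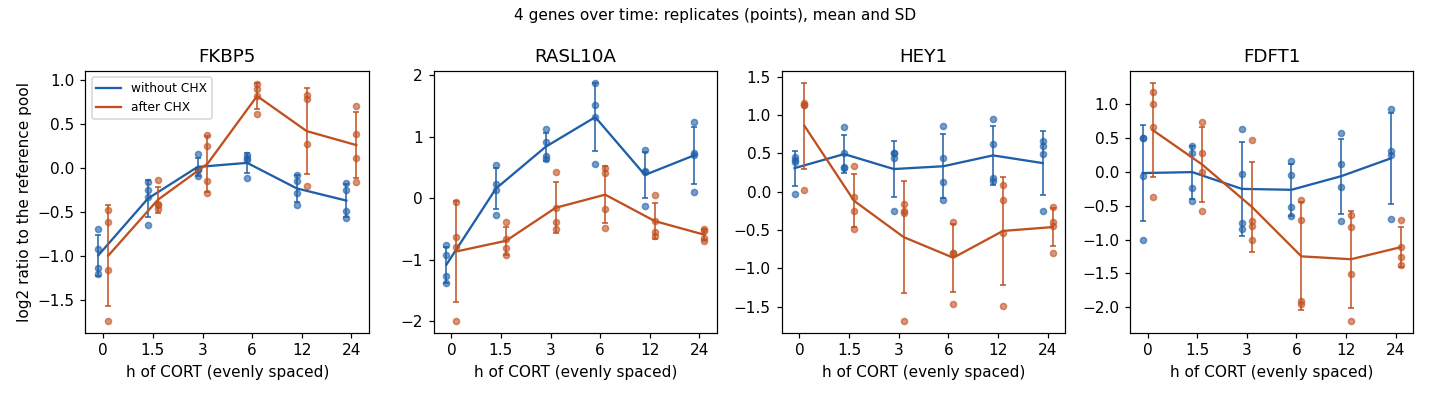
Log2 ratio to the reference pool of FKBP5, RASL10A, HEY1 and FDFT1 against hours of CORT (evenly spaced), with 4 replicates per group as points and mean ± SD as lines and bars, without CHX (blue) and after CHX (orange); the genes were chosen after their values were seen. At 6 h FKBP5 stood at 0.06 without CHX and 0.82 after it, and RASL10A at 1.32 and 0.06.

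The fourth question was whether the response to CORT differed after CHX. The joint interaction test called 0 features (limma, smallest adjusted p = 0.0576, 528 at an unadjusted p under 0.05). The genes with the smallest joint p were CRIM1 (adjusted p = 0.0936), TGFBI (0.146), CCNYL1 (0.148), HPGD, SLTM, FOXC2 and PM5 (each 0.212), ADARB1 (0.22), BRPF3 (0.236) and SLC12A4 (0.3). CRIM1 differed from its 0 h group at 24 h by -0.40 without CHX and by 1.11 after it. RASL10A, called at 3 to 24 h without CHX, differed after CHX by 0.17, 0.71, 0.93, 0.49 and 0.27 from 1.5 to 24 h, none past the threshold. Its joint test gave an adjusted p of 0.69, so that a different response was not shown. Single-time interactions gave 1 feature at 6 h, an unnamed probe, and 0 at the other times (unadjusted p under 0.05: 348, 162, 564, 385 and 753 from 1.5 to 24 h). The joint count of 0 depended on the setting: it was 67 with array weights, 117 with weights from complete features, 104 with the axis score as a covariate and 2 with quantile normalisation. Other settings also raised the joint count, a block for the replicate number among them, and are given with the processing. Leaving out 1 array gave up to 20, without replicate 2 of CORT 12 h after CHX, and 1 to 4 without untreated replicate 2, CHX replicate 2, CORT 6 h replicate 4 or CORT 24 h replicate 3. After CHX, it gave 1 to 4 without CORT 3 h replicate 3, 6 h replicate 4 or 24 h replicate 1, 2 or 3.

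A response with and without CHX is the pattern sought for genes that need no new protein. It rests on the assumption that CHX blocked translation for as long as CORT acted, which was not measured here. At 1.5 h 0 features were called in both, and at 3 h FKBP5 and probe_13.4.10 were called higher in both (expected from independent lists 8e-04). At 6 h, FKBP5, IMP3, LRRN3, PRRG3 and 2 unnamed probes were called higher in both (expected 0.083). At 12 and 24 h 0 features were called in both. Calls after CHX were also looked up in the arrays without CHX, which share none with them. At 6 h 55 of 85 features that rose and 35 of 44 that fell had the same sign there, at 12 h 45 of 59 and 58 of 67, and at 24 h 44 of 72 and 133 of 179, with medians there between -0.22 and 0.11. Of all features, 46.7 to 53.3% had the sign asked for. The medians after CHX were 0.81 and -0.67 at 6 h, 0.72 and -0.9 at 12 h, and 0.66 and -0.81 at 24 h. The features were chosen by their calls after CHX, which by itself tends to make those medians the larger. The overlap of 2 at 3 h was 0 without any one of untreated replicates 1, 2 or 4, CORT 3 h replicates 2, 3 or 4, CHX replicate 3 or CORT 3 h after CHX replicate 3.

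Hormone genes gave no calls in the fit reported, though some were called in other settings. GH, growth hormone, which CORT is known to raise in embryonic chicken pituitary cells, differed from untreated by 0.16 at 24 h of CORT (95% interval -0.28 to 0.59; -0.2 without CORT 24 h replicate 1) and from CHX alone by 0.31 at 24 h of CORT after CHX (-0.13 to 0.74). PRL, prolactin, differed from untreated by 0.42 at 24 h (-0.27 to 1.1), POMC by 0.16 (-0.18 to 0.49), and FSHB, the follitropin subunit, by -0.44 (-0.73 to -0.15, adjusted p = 0.999). POU1F1, the transcription factor of growth hormone, prolactin and thyrotropin cells, differed by 0.01 (-0.29 to 0.3). TSHB differed from CHX alone by -0.97 at 24 h of CORT after CHX (-1.55 to -0.39, adjusted p = 0.0601). It passed there with array weights (adjusted p = 0.0085), with the axis score as a covariate (0.0372) and without replicate 3 of that group (0.0144) or CHX replicate 4. Over all alternatives its adjusted p ranged from 0.00685 to 0.3. With weights from complete features, TSHB at 12 h after CHX (0.0464) and GH at 3 h after CHX (0.46, adjusted p = 0.0406) passed too. The direction check gene DUSP1 differed by 0.09 at 24 h (-0.22 to 0.39). In the secretory list, SCG3, a granin of secretory granules, fell at 24 h after CHX from 0.26 ± 0.07 to -1.31 ± 0.64 (difference -1.57, SE 0.26, adjusted p = 0.000277).

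The other 10 lists were not called in any of the 11 comparisons. Their smallest adjusted p were 0.0826 for cell cycle genes and for oxidative phosphorylation, 0.0899 for interferon and antiviral genes, 0.205 for red blood cell markers, 0.222 for steroid receptor and chaperone genes, 0.291 for pituitary transcription factors, 0.348 for neuronal and glial markers, 0.398 for immune cell markers, 0.527 for cartilage and muscle markers and 0.662 for NF-kB and cytokine genes. Of the 39 list calls, 27 held with an estimated correlation and 21 with fry, and in none did median, mean and test differ in sign.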

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

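The tests against other groupings of the samples and the test of members that vary together were chosen only after the results were seen. In 8 of 165 sets of 4 values of named genes, and in 4 of 48 sets of array measures, 1 replicate lay far from the other 3 (the gap to its nearest neighbour, over the range, was above Dixon's critical value), and chance gives this in 5% of sets.

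In CHX alone, replicate 1 held KLF11 at 2.58 (others -0.13 to 0.3; without this array its decreases at 6 and 12 h after CHX were -0.6 and -0.81 in place of -1.23 and -1.44), HEY1 at 0.02 (others 1.13 to 1.15) and SALL1 at -0.05 (others 0.61 to 0.69), and replicate 3 held AGTR1 at 1.78 (others 0.57 to 0.65). GH stood at 1.22 in CORT 24 h replicate 1 (others -0.24 to -0.1), and without this array its difference from untreated was -0.2 in place of 0.16. In CORT 1.5 h replicate 1, DUSP1 stood at 0.26 (others -0.23 to -0.19) and POU1F1 at 0.05 (others 0.27 to 0.31), and FSHB at -0.24 in replicate 1 of CORT 12 h after CHX (others -0.06). The SD of the array was 0.3007 for CORT 3 h replicate 2 (others 0.3188 to 0.3206) and 0.3047 for CORT 24 h replicate 4 (others 0.3218 to 0.3223). The score on the main axis of spread was -0.2737 for CORT 24 h replicate 1 (others 0.0595 to 0.1104) and -0.1619 for replicate 1 of CORT 24 h after CHX (others 0.0364 to 0.0763). A difference between cells with and without CHX was tested by interaction, and 1 feature, an unnamed probe, passed at 6 h.

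The first pattern weighed was the larger number of features called after CHX (251) than without it (2) at 24 h. With the axis score as a covariate the counts were 724 and 9, and with a CHX array left out the lowest count was 116. The larger count after CHX thus remained, which argues against a single CHX array as the whole cause. The axis was taken from the spread of these same arrays, so fitting it tends by itself to raise counts. Both counts rose with the covariate, and its mean differed between groups. As mean ± SD, on the scale of the covariate, it was 3.01 ± 19.25 with CHX alone and -9.63 ± 12.07 with CORT for 24 h after CHX. Untreated and CORT for 24 h without CHX stood at 6.1 ± 21.41 and 3.98 ± 20.32. The test of the axis therefore cannot decide. Time in culture after CHX, or longer exposure to CHX if it was not removed, cannot be told apart from CORT. The reason is that 0 arrays of CHX alone were kept for a later time. Whether CHX changed the response to CORT stays open. Of single features, 0 passed the joint interaction test in the fit reported, a count that depended on the setting. Some gene lists changed differently from 0 h after CHX than without it (given under the other observations). Those contrasts do not separate CORT from time after CHX.

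The second pattern was the lower ribosomal protein list in 6 comparisons at the preset correlation. With the axis score as a covariate 4 comparisons called it lower, 3 of these 6 and CORT at 1.5 h, which leaves the axis undecided. With no effect added, 52.3% of the tests of this list were called, so that members varying together may explain the calls. Other called lists also had raised shares: 20.5% for proteasome genes, 10.9% for fibroblast and matrix markers, 7.7% for heat shock proteins, and 6.4% each for cholesterol synthesis and endothelial markers. With an estimated correlation the share was 0.5% for cholesterol synthesis and 0% for the ribosomal and these other lists. Dye bias that depends on signal cannot be told apart, since 0 columns of spot intensity were used here. No biological explanation was tested.

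The third pattern was the immediate-early list, higher with CHX alone and lower with CORT after CHX, 2 comparisons that share the CHX arrays. With the CHX arrays divided between them, all 6 divisions gave both directions, and the largest adjusted p with CHX alone was 6.15e-09 with a CHX array left out, which argues against a chance level of the shared arrays and against a single array. Relative to untreated, the list mean was 0.37 with CHX and 0.25, 0.15, 0.1, 0.14 and 0.01 at 1.5 to 24 h of CORT after CHX. A candidate explanation is a superinduction by CHX that faded, but fading with time in culture and repression by CORT were not separated by the design.

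Other groupings of the 8 arrays in a comparison were counted. The real grouping was the only 1 of 35 with as many calls for CORT at 6 h (11 features, highest other grouping 0). The same held after CHX at 6 h (129 and 4), 12 h (126 and 51) and 24 h (251 and 11). With 35 groupings this is the lowest share the test can give, and it was not adjusted over the 11 comparisons. Neither the other groupings nor the shuffled draws below were held to balanced replicate numbers, as the real groups are. The real grouping is thus not 1 among like groupings, and these shares bear only loosely on chance. Chance was not excluded for these counts. The real grouping was also the only 1 of 35 for CORT at 3 h (3 and 1), 12 h (2 and 0) and 24 h (2 and 0) and for CHX alone (2 and 0). Those counts are no larger than the 3 calls that arrays reassigned with no change added gave in some comparison, so that chance stays open for them. Nor could chance be excluded after CHX at 1.5 h (2 and 4, 2 of 35) or 3 h (3 and 1091, 2 of 35). For CORT at 1.5 h the real count was 0 and the highest other 0, and a count of 0, which all 35 groupings reach, says nothing about chance. The 1091 features of another grouping at 3 h after CHX point to a structure of the samples other than treatment. Whether the replicate numbers made it was not tested. For the joint interaction the real count was also 0, which all 100 draws with shuffled CHX labels reach, so that nothing follows about chance; the highest draw gave 542, which points to a structure of the samples. For the overlap at 1.5 or 3 h the real count was 2 and the highest draw 0. Of 100 draws 1 had as many, the real one included, which is the lowest share this test can give. The 3 h sets of calls behind the overlap share no arrays, and independent lists of their size would share 8e-04 features. The draws, however, were not balanced over the replicate numbers, so chance was not excluded for the overlap either.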

How the results depend on the processing

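Leaving out the arrays numbered 1, the axis covariate, zeros as missing, all features as list background and weights from complete features were tests chosen after seeing the data. Counts are given for CORT at 1.5, 3, 6, 12 and 24 h, for CHX alone, and for the same times after CHX. The counts as reported were 0, 3, 11, 2, 2, then 2, then 2, 3, 129, 126, 251, with 0 joint interactions and 2 shared calls at 1.5 or 3 h. The cause of the shifts below was not tested, except that leave-outs and fitting fewer groups use fewer samples.

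A block for the replicate number was fitted. With group means removed, arrays with the same number correlated on average at 0.56, 0.18, 0.09 and 0.52 for numbers 1 to 4, with lowest values of -0.34, -0.52, -0.44 and 0.28, so that not every pair was alike. Yet for 40 of 48 arrays the closest array of another group had their own number, a hint from the data, not the design, that the numbers share something. With this block the counts were 5, 4, 13, 2, 5, then 6, then 2, 29, 375, 547, 753, with 31 joint interactions.

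Median centring gave 0, 2, 7, 1, 1, then 2, then 1, 2, 112, 109, 222, with 1 shared call. Quantile normalisation gave 2, 3, 10, 1, 1, then 3, then 1, 9, 134, 123, 261, with 2 joint interactions. Fitting only the groups compared gave 0, 2, 7, 0, 0, then 0, then 0, 0, 15, 1, 139, with 0 shared calls. Single probes gave 0, 2, 8, 0, 2, then 3, then 2, 3, 154, 168, 317, with 1 shared call. Values on all 48 arrays gave 0, 3, 5, 0, 2, then 2, then 2, 3, 99, 103, 211, with 1 joint interaction. No filter gave 0, 1, 8, 0, 2, then 3, then 3, 3, 135, 118, 237, with 0 shared calls. The variance trend gave 0, 2, 11, 2, 2, then 2, then 2, 3, 130, 129, 255, with 1 shared call.

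Array weights gave 34, 7, 13, 2, 4, then 4, then 6, 1477, 283, 430, 784, with 67 joint interactions. Weights from complete features gave 107, 12, 21, 2, 12, then 9, then 8, 2159, 321, 469, 877, with 117 joint interactions and 8 shared calls. Leaving out the arrays numbered 1 gave 0, 2, 1, 1, 2, then 0, then 2, 0, 60, 163, 315, with 0 shared calls. The axis covariate gave 7, 12, 23, 7, 9, then 12, then 7, 21, 525, 478, 724, with 104 joint interactions and 5 shared calls. Zeros as missing gave 127, 126 and 257 at 6 to 24 h after CHX.

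Leaving out 1 array gave ranges of 0 to 1, 1 to 3, 3 to 12, 0 to 1 and 0 to 3 for CORT, 0 to 2 for CHX alone, and 0 to 8, 1 to 21, 42 to 150, 28 to 181 and 94 to 282 after CHX. It gave 0 to 20 joint interactions, highest without replicate 2 of CORT 12 h after CHX, 0 to 2 shared calls and 36 to 52 list calls. At 1.5 h after CHX the count of 8 came without replicate 1 of that group, and at 3 h after CHX counts of 7 and 9 came without CHX replicates 2 and 4.

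Of the list calls, 39 as reported, 27 were made with an estimated correlation, 24 with fry, 44 against all features and 33 with the axis covariate. Of list calls across settings other than leave-outs, 196 stayed past the threshold and 38 did not, and with 1 array left out 271 did and 41 did not. The immediate-early list with CHX alone, the glucocorticoid-induced list at 1.5 and 3 h of CORT, and the cholesterol list at 6, 12 and 24 h after CHX passed in every setting run. Of the values of named genes and probes, 1820 kept their direction and side of the threshold in settings other than leave-outs, 117 lost a call, 9 gained one, 51 changed sign without a call in either setting, and 1 called value turned sign: a single probe of SYDE2 at 6 h after CHX, at 0.03. With 1 array left out, 979 kept both, 160 lost a call, 2 gained one and 75 changed sign without a call. Signal over background could not be used here as a limit on depth, since no spot intensities were used.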

Other observations

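The list tests of the interaction were chosen after the results were seen. CHX alone was not kept for later times, so these tests cannot tell a different response to CORT from time after CHX. Although 0 single features passed the joint interaction test, the change of cholesterol synthesis genes from 0 h was lower after CHX than without it at 6 h (mean difference -0.378, adjusted p = 1.7e-05, and 0.00549 with an estimated correlation), 12 h (-0.343, adjusted p = 0.000102, and 0.0172) and 24 h (-0.405, adjusted p = 0.000102, and 0.017). The immediate-early list was lower in the same way at 3 h (-0.185, adjusted p = 0.00424, and 0.00549), 6 h (-0.185, adjusted p = 0.0261, and 0.0244), 12 h (-0.2, adjusted p = 0.0254, and 0.0213) and 24 h (-0.342, adjusted p = 0.000102, and 0.000112), and the unfolded protein response list at 12 h (-0.245, adjusted p = 0.00475, and 0.0178). The immediate-early list started from a raised level after CHX. Relative to untreated its mean was 0.37 with CHX alone, 0.01 with CORT for 24 h after CHX and -0.03 with CORT for 24 h without CHX. A fading of that raised level would give the same sign without a different response to CORT. Other calls at the preset correlation were lost with an estimated correlation: cholesterol synthesis at 1.5 and 3 h (adjusted p = 0.249 and 0.131), heat shock proteins at 1.5 h (0.397), cell cycle genes at 12 h (0.0759), and the unfolded protein response list and ribosomal proteins at 24 h (0.0759 and 0.781). For the fibroblast and matrix markers at 24 h the adjusted p was 0.00107, but adjusted p = 0.0808 with an estimated correlation, and for the glucocorticoid-induced list at 12 h it was 0.0451, but adjusted p = 0.175 with an estimated correlation.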
